A study of Mus musculus with 6 samples.

How the data were processed

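Primary fibroblasts of the mammary fat pad were taken from healthy females of 8 to 12 weeks of 2 inbred strains, BALB/c and C57BL/6, and kept in culture for 4 days. Per the labels, the tissue was digested with collagenases and DNase, red blood cells were lysed and the cells were plated on collagen. The design text also names a magnetic separation, whose target is not given in the sources used here. Libraries covered the 3′ ends of polyadenylated RNA. Samples were grouped by the strain given in their labels, with 3 biological replicates per strain, and no batch is given in the sources used here.

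The authors deposited 1 table of raw counts per gene symbol with a column for each of the 6 libraries. Per the submitters' processing notes, bcl2fastq, STAR 2.4.2a, HTSeq and the mouse genome build mm10 were used, with no settings, order or annotation given. Whether molecular identifiers were collapsed, whether counting used the strand and how reads with several matches were treated are not given in the sources used here. The table lists 12023 genes, and each reaches at least 6 counts in at least 1 library, so lower genes are not among those analysed here. The header line of the table separates its first sample names by spaces, and columns were matched to samples by the library names in the labels. A 3′ count depends little on transcript length. Counts of genes with near-identical copies depend on how the counting split or dropped shared reads, and reads of BALB/c alleles that differ from the C57BL/6 reference can be lost in alignment.

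Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by strain, which left 8752, libraries were scaled with TMM factors of 0.866 to 1.06, and a quasi-likelihood fit with robust dispersion and strain as the only term was tested two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 41.1%. Differences are log2, BALB/c minus C57BL/6, and the standard error of a log2 difference is its size divided by the square root of the F statistic. CPM are counts relative to the TMM-scaled library total, given as mean ± SD over 3 libraries. Gene lists were tested with limma 3.58.1's camera at a preset correlation between genes of 0.01, for the 29 of 31 lists with at least 3 tested members, adjusted over the lists. The count of genes of a list past the threshold is given over all genes and adjusted over the list alone. With the correlation estimated for each list, 0 of the 6 lists that passed held. The lowest adjusted p was 0.297, for the glycolysis and hypoxia list. The estimated correlation of that list was -0.0322, below the preset 0.01, so correlation between its genes does not account for its loss. Rotation tests with fry gave 0 lists, with a lowest adjusted p of 0.0680 for movement in 1 direction and 0.0645 for change in either direction. Library structure was described by principal components and Pearson correlations across genes of log2 CPM with a prior count of 2, which are descriptions, as genes are not independent replicates.

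The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Genes were named as the 8 higher and 8 lower with the largest log2 difference among those past the threshold whose strains did not overlap, with a mean log2 CPM of at least 5, leaving out predicted genes, clones and pseudogenes by symbol. Every tested member of the lists of NK activating ligands and of described strain differences was named, with H2-K1, H2-D1, H2-T23 and B2m. From each other list up to 2 members per direction past the threshold were named, or the 2 with the highest mean log2 CPM where none passed. Of the genes the rule takes, 1 is not reported here. Genes named beyond the rule are marked as such or are those that passed over their list alone.

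Symbols were placed on GRCm38, the same assembly as mm10, with GENCODE vM21, which located 11973 genes, or 99.6%, 121 of them through another symbol. Near-identical copies were searched with BLAST+ 2.17.0 for the last 500 nt of 1 transcript per gene, the longest protein-coding one where present. The limits were an identity of at least 95% over at least 60 nt. Other 3′ ends of a gene were not searched. Exons that overlap those of another gene were listed from the same annotation. Pairs of libraries of a strain differed by far more than sampling noise, with a chi-square per degree of freedom of 10.8 to 57.2 over 5541 genes, so no pair was taken as copies of 1 library. This does not show what separates the libraries, and each counted as a biological replicate per its label. Total counts of 1035485 to 4665896 set the precision of counting, and the spread between libraries comes on top of it. Counting intervals are exact at 95%, and they and the floor of 3 counts cover counting error only.

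The test was tried on simulated counts with the means and library sizes of the comparison of the strains for 8752 genes. It called 2 of 61 genes changed 2-fold, 25 of 64 changed 4-fold, 63 of 65 changed 16-fold and 6 of 8094 unchanged genes, so that 2-fold differences were mostly missed at this depth and spread. Alternatives were RLE and upper quartile scaling, library totals, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 50 counts, ribosomal protein genes left out, the replicate number as a block, and each library left out in turn. Library quality weights in limma-voom, a per-library spline of GC content and length as an offset, and the principal components with each library left out were added after the data were seen.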

Results

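Fibroblasts grown from the mammary fat pad of healthy females of 2 inbred mouse strains, BALB/c and C57BL/6, were compared after culture. The design text states the aim as the baseline difference in expression between the normal mammary fibroblasts of the strains, in a series about how fibroblasts of tumours affect natural killer (NK) cells. Each strain gave 3 biological replicates from mice of 8 to 12 weeks, cultured for 4 days before RNA was taken. The measurement was a count of reads per gene from the 3′ ends of polyadenylated RNA. The deposited table listed 12023 genes in 6 libraries. Total counts were 1458182, 2713611 and 1035485 in BALB/c replicates 1, 2 and 3, and 1521933, 1295349 and 4665896 in C57BL/6 replicates 1, 2 and 3. In the shallowest library 3 counts correspond to 2.90 CPM (counts scaled to library size), and in the deepest to 0.612 CPM.

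The libraries did not group by strain. C57BL/6 replicate 1 lay alone on the first principal component of log2 CPM, which held 68.2% of the variance, and its mean correlation with the other 5 libraries was 0.779 against 0.870 to 0.910 for the others. In that library 514 of 5541 genes with a mean of at least 50 counts lay at least 4-fold below both other C57BL/6 libraries, among them Npm1, a nucleolar chaperone, with 21 counts against 1024 and 2239. Npm1 was also low in BALB/c replicate 2, with 139 counts against 1234 and 498 in BALB/c replicates 1 and 3. GC content and transcript length explained 50.3% of the variance of its deviations, against 5.06% to 21.1% in the other libraries. The highest correlation was 0.947, between BALB/c replicate 3 and C57BL/6 replicate 3. BALB/c replicate 1 and C57BL/6 replicate 2 had 0.945, and BALB/c replicates 2 and 3 had 0.943. BALB/c replicate 1 and C57BL/6 replicate 2 both held few counts of mammary epithelial markers, 0.229% and 0.352% of all counts, where the other 4 libraries held 1.03% to 1.79%.

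**Figure D1:**
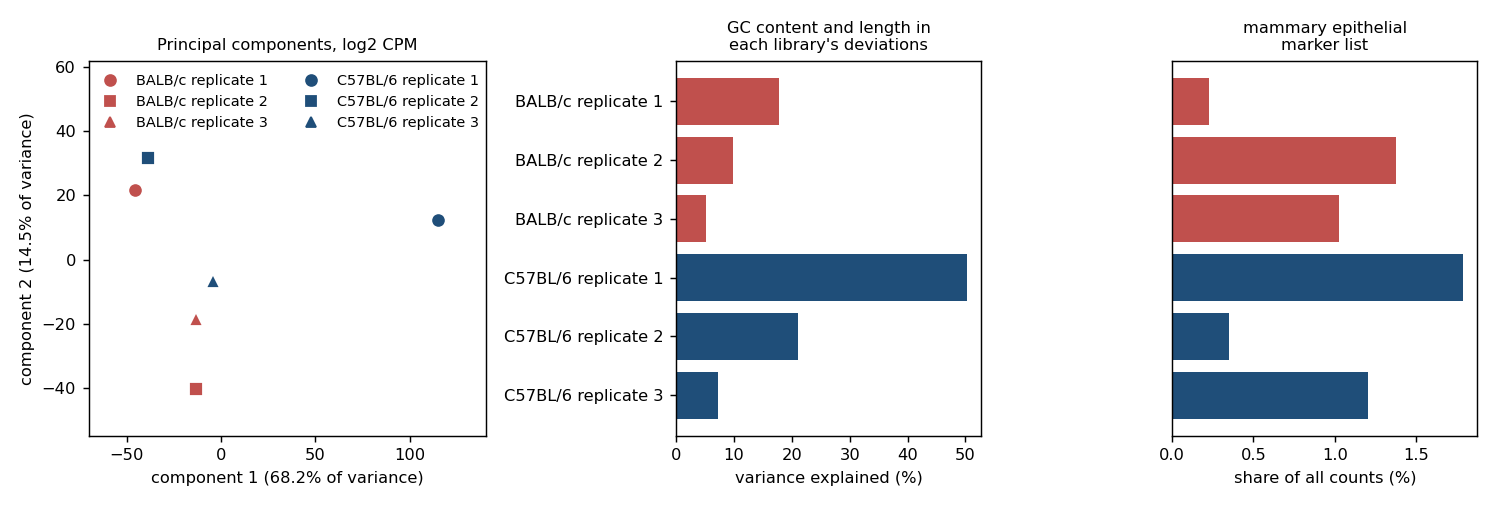
Left, each library on the first 2 principal components of log2 CPM over 8752 genes, with the share of variance on each axis. Middle, the percent of the variance of each library's deviations explained by GC content and length, and right, the percent of all counts in the mammary epithelial marker list, with 1 bar per library; C57BL/6 replicate 1 stands alone on component 1 and has the longest bar for GC content and length, 50.3%.

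The question of the series was which genes differed between the strains. Of 8752 tested genes, 18 differed at an adjusted p under 0.05, 6 higher and 12 lower in BALB/c, and all 18 by at least 1 on the log2 scale. Cap1, a regulator of actin filaments, rose from 29.2 ± 12.9 CPM in C57BL/6 to 503 ± 57.2 CPM in BALB/c (SD, n = 3 each). Plau, the urokinase-type plasminogen activator, was at 71.6 ± 29.1 CPM in BALB/c and 3.69 ± 1.25 CPM in C57BL/6. Rpl29, a ribosomal protein gene, fell from 1691 ± 397 CPM in C57BL/6 to 32.5 ± 16.6 CPM in BALB/c, and Ly6a, which encodes the surface protein Sca-1, from 267 ± 141 to 15.0 ± 4.39 CPM. In all 18 genes every BALB/c library lay on the same side of every C57BL/6 library. Picking the genes by their difference in these same libraries makes this likely, so it adds no support. Over all tested genes the strains did not overlap in 995, or 11.4%, where chance gives 10%.

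The log2 difference, BALB/c minus C57BL/6, with its standard error, was 4.10 ± 0.40 for Cap1 (adjusted p = 0.0202), 4.24 ± 0.48 for Plau (adjusted p = 0.0275) and 5.66 ± 0.63 for Serpina3h (adjusted p = 0.0275), from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Serpina3h belongs to a family of serine protease inhibitors and is annotated as a transcribed unprocessed pseudogene. It was at 100.2 ± 24.5 CPM in BALB/c and 1.65 ± 1.44 CPM in C57BL/6. By the same test the log2 difference was -5.79 ± 0.38 for Rnaset2b, a ribonuclease of the T2 family (adjusted p = 0.00499), -4.45 ± 0.31 for Pdxdc1 (adjusted p = 0.00499), -5.72 ± 0.50 for Rpl29 (adjusted p = 0.0154) and -5.07 ± 0.56 for Tcn2, a carrier of vitamin B12 (adjusted p = 0.0275). C1s1, a serine protease of the complement system, was lower by -3.59 ± 0.41 (adjusted p = 0.0275), Pop4, a subunit of ribonuclease P, by -2.44 ± 0.29 (adjusted p = 0.0275), and Ly6a by -4.16 ± 0.55 (edgeR adjusted p = 0.0493). Ly6a was the least stable of the 18 calls, past the threshold in 6 of 17 alternatives, and its call was lost with upper quartile scaling, library totals alone, limma-voom and a mean of at least 50 counts, and with ribosomal genes left out.

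On GRCm38 these genes lay on different chromosomes. Cap1 was at chromosome 4, 122859047 to 122886056, Plau at chromosome 14, 20836660 to 20843385, and Serpina3h at chromosome 12, 104247905 to 104253669. Rnaset2b was at chromosome 17, 6970634 to 7011299, Pdxdc1 at chromosome 16, 13833148 to 13903131, Rpl29 at chromosome 9, 106429454 to 106431568, and Tcn2 at chromosome 11, 3917192 to 3932159. C1s1 was at chromosome 6, 124530345 to 124542359, Pop4 at chromosome 7, 38261996 to 38271423, and Ly6a at chromosome 15, 74994877 to 74998031.

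The remaining 8 genes past the threshold had lower counts, fell outside the rule for named genes and are named here after their values were seen. Tmem87a, Gbp2b, an interferon-inducible GTPase, and AI506816 were higher in BALB/c. Gbp2b had 79 counts in BALB/c against 1 in C57BL/6, a ratio of 111 per effective library size with a 95% counting interval of 19.4 to 4440. Il4ra, the alpha chain of the interleukin 4 receptor, Prcp, Stmn1, which encodes a destabiliser of microtubules, Pusl1 and Trim12a were lower in BALB/c. Il4ra had 8 counts in BALB/c and 263 in C57BL/6, with a log2 difference of -4.51 ± 0.41 (edgeR adjusted p = 0.0154). Trim12a had 0 counts in BALB/c and 212 in C57BL/6, which makes it at least 50.3-fold lower in BALB/c against a floor of 3 counts taken over the group, while its 95% counting interval reaches down to 40.5-fold.

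Of the 18 genes, 6 met the search limits for a near-identical copy in the annotated transcripts, so their counts are uncertain: Rpl29 with 34 copies, Rnaset2b with its neighbour Rnaset2a, C1s1 with C1s2, and Ly6a, Stmn1 and AI506816 with 1 each. The longest match covered 430, 500 and 442 nt in Rpl29, Rnaset2b and C1s1. In Ly6a, AI506816 and Stmn1 it was a short stretch of 116, 87 and 60 nt, that of AI506816 in Chd9. Exons of 9 of the 18, or 50%, overlapped exons of another annotated gene, against 37.7% of the other tested genes (Fisher's exact two-sided p = 0.333). Cap1 overlapped Ppt1 and Pdxdc1 overlapped Ntan1, both on the opposite strand. Ppt1 had a log2 difference of -1.88 and Ntan1 one of 1.07, opposite in sign to Cap1 and Pdxdc1 and not past the threshold in edgeR. Ppt1 passed with DESeq2 (adjusted p = 0.0169) and with limma-voom's library quality weights (0.0365). Ints11, which overlapped Pusl1 on the opposite strand and was the one other partner tested, had -0.19, the same sign as Pusl1. The count of genes depended on the libraries. Without C57BL/6 replicate 1 edgeR called 25 genes, 17 of the 18 among them, without BALB/c replicate 1 it called 4, and without C57BL/6 replicate 2 it called 5. Without BALB/c replicate 2, BALB/c replicate 3 or C57BL/6 replicate 3 it called 0. There 205 of 8993, 226 of 9143 and 261 of 9003 tested genes had an unadjusted p under 0.05. These shares lie below the 0.05 that p-values would give with no difference. With all 6 libraries 338 genes, or 3.86%, had an unadjusted p under 0.05, also below that share. The split of 6 higher and 12 lower became 5 and 6 with library totals alone, 15 and 16 with a GC and length offset, and 25 and 32 with library quality weights, and DESeq2 called 71 genes, 25 higher and 46 lower, where limma-voom called 3.

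**Figure D2:**
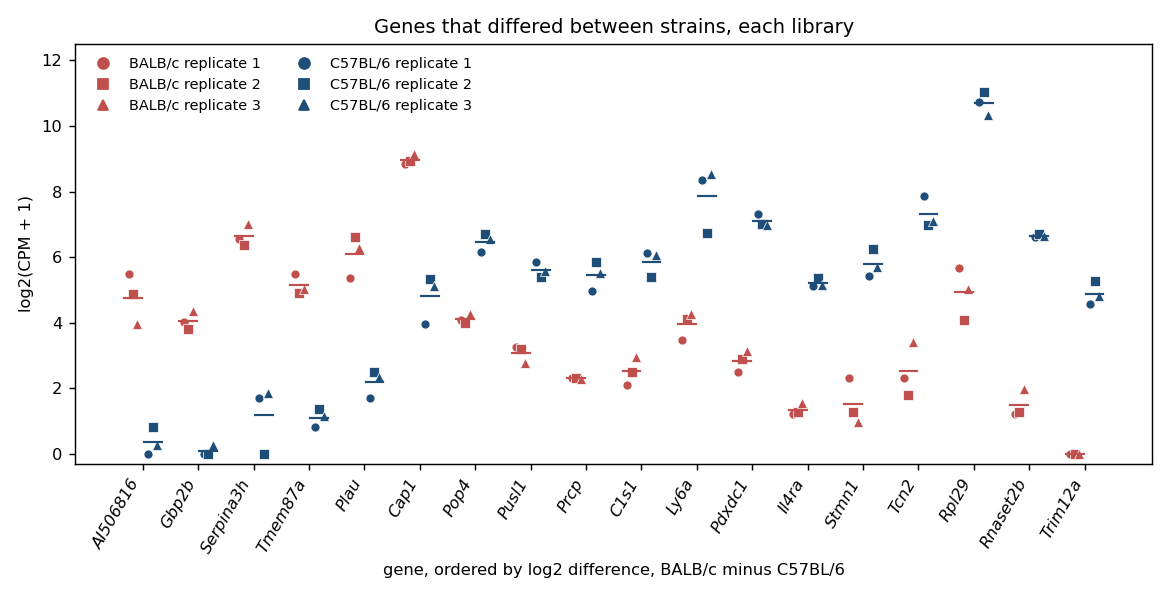
The 18 genes with an adjusted p under 0.05, ordered by log2 difference, with log2(CPM + 1) on the vertical axis; points are the 3 libraries of each strain and lines their means. The libraries of the strains do not overlap in any of the 18 genes, and Trim12a is at 0 in the 3 BALB/c libraries.

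Calls of members of the gene lists, over all genes or over the list alone, are from edgeR with all 6 libraries unless another setting is named. Where a named list member did not pass over all genes there, those of the 17 alternatives in which it did are given. It did not pass in the others. Between sets of 3 libraries drawn without regard to strain, DESeq2 called 34 and 22 genes in some and 0 to 3 in the others. In edgeR all of these gave 0. The adjusted p of DESeq2 is therefore weak evidence here. Library quality weights were not run on such sets. They were 0.157 for C57BL/6 replicate 1 and 3.35 for C57BL/6 replicate 3, so the C57BL/6 side rests mostly on replicate 3 there. Ligands of NK cell receptors showed no difference past the threshold over all genes in edgeR. Raet1e was the one ligand of the activating receptor NKG2D that could be tested, with 12.6 ± 8.40 CPM in BALB/c and 12.2 ± 11.7 CPM in C57BL/6 (SD, n = 3 each), and its exons overlap those of Raet1d and H60b. The standard error of its log2 difference was 1.04, about the size of a 2-fold difference, so such a difference could not be told from none. H60a, H60b, H60c, Raet1a, Raet1b, Raet1c, Raet1d and Ulbp1 are not among the genes of the table used here. Their absence does not show that they were not expressed, since reads of BALB/c alleles that differ from the C57BL/6 reference can be lost. The comparison thus covers 1 of the 9 listed NKG2D ligands and not the group. Among ligands of DNAM-1, TIGIT and other activating receptors, 7 were tested and 0 passed, adjusted over the list alone or over all genes. Pvr and Nectin2, the ligands of DNAM-1, had log2 differences of -0.30 ± 0.23 and -0.48 ± 0.22, Icam1, the ligand of LFA-1, -1.20 ± 0.41, Nectin1 -0.55 ± 0.38, Nectin4 -0.06 ± 0.48, Nectin3 0.24 ± 0.39 and Tnfsf9 0.11 ± 0.36. The list as a whole had an adjusted p of 0.108 in limma's camera test. Icam2, Vcam1, Clec2f, Il15 and Il18 were below the count filter, and Cd48, Cd70, Tnfsf4, Clec2g, Clec2i and Il12a are not among the genes of the table used here.

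Among 17 inhibitory ligands and immune checkpoints 0 passed over all genes in edgeR and 1 passed adjusted over the list alone. This was Cd200, the ligand of the inhibitory receptor CD200R, at 57.1 ± 24.6 CPM in BALB/c and 2.71 ± 2.74 CPM in C57BL/6, with a log2 difference of 4.39 ± 0.78 (edgeR adjusted p over all genes = 0.170). It passed over all genes with DESeq2 (adjusted p = 3.0e-07), library quality weights (0.00968) and the GC and length offset (0.0492). It is named here after its values were seen. The classical class I genes H2-K1 and H2-D1 had log2 differences of -0.16 ± 0.24 and 0.42 ± 0.26, their light chain B2m -0.10 ± 0.48, and H2-T23, which encodes the NKG2A ligand Qa-1, -0.88 ± 0.28. H2-D1 has 3 near-identical copies and H2-T23 has 29. Here too, reads of BALB/c alleles that differ from the C57BL/6 reference can be lost, so similar counts do not show equal expression. Of 17 tested genes of MHC class I and antigen processing, the chaperone Calr among them at -0.29 ± 0.36, 0 passed over all genes or adjusted over the list alone. The inhibitory list had a camera adjusted p of 0.836 and the class I list one of 0.417. Of 40 interferon response genes 0 passed by either adjustment. Bst2, an interferon-induced antiviral protein, had a log2 difference of -0.71 ± 0.28 and Isg15 one of -0.21 ± 0.51. The interferon list had a camera adjusted p of 0.208, and of 2.8e-04, lower in BALB/c, without C57BL/6 replicate 1.

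Among genes listed beforehand for a described allele or copy number difference between the strains, 9 were tested. Ly6a passed over all genes, and Ly6a, Ly6c1 and Cdkn2a passed adjusted over the list alone. Ly6c1, the neighbour of Ly6a, had 9 counts in BALB/c and 263 in C57BL/6, with a log2 difference of -4.23 ± 0.90 (adjusted p = 0.299 in edgeR and 0.00117 in DESeq2), and it has 2 near-identical copies. Cdkn2a, which encodes cell cycle inhibitors of senescence, was higher in BALB/c by 1.41 ± 0.43 (edgeR adjusted p = 0.929). Nnt, a mitochondrial transhydrogenase with a known deletion in C57BL/6J mice, had a log2 difference of 0.60 ± 0.52, Apobec3 -0.77 ± 0.48, Ide 0.85 ± 0.43, Prkdc -0.26 ± 0.45 and Wdfy1 -0.10 ± 0.70. Ifi202b and Oas1b were below the filter, and the other members, H2-Ea, H2-L, Tyr, Tyrp1, Gvin1, Nlrp1b and Klrb1c among them, are not among the genes of the table used here. The list had a camera adjusted p of 0.151.

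Genes of the contractile myofibroblast state were lower in BALB/c as a list. Of 30 tested, 22 were lower and 8 higher, with a median log2 difference of -0.43 (camera adjusted p = 3.7e-04, and adjusted p = 0.407 with an estimated correlation). None passed over all genes in edgeR, and Cnn1 and Actg2, both smooth muscle genes, passed adjusted over the list alone, and over all genes with DESeq2 (adjusted p = 0.00145 and 0.00611). Pericyte and smooth muscle markers, which share both genes, moved with this list. Cnn1, calponin, was at 180 ± 28.8 CPM in BALB/c and 428 ± 70.3 CPM in C57BL/6, with a log2 difference of -1.25 ± 0.25 (edgeR adjusted p = 0.239). Actg2, smooth muscle gamma actin, had a log2 difference of -1.42 ± 0.29 (edgeR adjusted p = 0.278). Tpm1, a tropomyosin, had a log2 difference of -0.54 ± 0.25. The per-library mean of the list, relative to the mean of the 6 libraries, was 0.10, -0.38 and -0.00 in BALB/c replicates 1, 2 and 3 and -0.49, 0.57 and 0.20 in C57BL/6 replicates 1, 2 and 3, so that C57BL/6 replicate 1 lay below the BALB/c libraries.

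The matrix lists did not pass the camera test with all 6 libraries, and leaving out a library changed this. Among 19 collagens the camera adjusted p was 0.170, with log2 differences of -0.01 ± 0.83 for Col1a2, a fibrillar collagen, and -1.09 ± 0.32 for Col4a1, a basement membrane collagen. Among 41 matrix glycoproteins and proteoglycans it was 0.588, with 0.10 ± 0.53 for Sparc and 0.65 ± 0.49 for Fn1. Without BALB/c replicate 1 both were lower in BALB/c, with camera adjusted p of 0.00528 and 0.0481, and without C57BL/6 replicate 1 the collagens had 0.00408. Neither list had a gene past the threshold over all genes or adjusted over the list alone. Of 42 matrix proteases, inhibitors and crosslinkers Plau passed over all genes, and Plau, Adamts4, an aggrecanase, and Tgm2, a transglutaminase, passed adjusted over the list alone. Adamts4 and Tgm2 were lower in BALB/c, by -2.29 ± 0.44 and -1.11 ± 0.23, and passed over all genes with DESeq2 (adjusted p = 0.00210 and 0.00125) and quality weights (0.0132 and 0.0252). Adamts4 also passed without C57BL/6 replicate 1 (0.0217). The list had a camera adjusted p of 0.105. It was lower in BALB/c with 0.00950 without BALB/c replicate 1, 1.1e-04 without C57BL/6 replicate 1, 0.0281 with limma-voom, 0.0400 with the GC and length offset and 0.0182 with quality weights. TGF-beta target genes had an adjusted p of 0.300, with 0 of 26 past the threshold by either adjustment.

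General fibroblast markers had a camera adjusted p of 0.886 and markers of progenitor fibroblasts of adventitia one of 0.713. Ly6a was the single gene of these lists past the threshold over all genes in edgeR, and Ly6c1 joined it in the progenitor list when adjusted over the list alone, and over all genes with DESeq2 (adjusted p = 0.00117). The median of the progenitor list was 0.43 and its mean -0.27, opposite in sign. Of 30 inflammatory fibroblast genes, Ly6c1 among them, 0 passed by either adjustment in edgeR (camera adjusted p = 0.623). Csf1, a growth factor of macrophages, had a log2 difference of -0.63 ± 0.24 and Lcn2, an iron-binding acute phase protein, one of -1.71 ± 1.01. Of 17 adipogenic genes 0 passed by either adjustment (camera adjusted p = 0.105), with 0.34 ± 0.24 for Plin2, a coat protein of lipid droplets, and -0.23 ± 0.24 for Cebpb.

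Markers of other cell types had counts in all 6 libraries. Of 19 macrophage and other leukocyte markers 18 were lower in BALB/c, with a median log2 difference of -1.08 (camera adjusted p = 2.5e-08, and adjusted p = 0.463 with an estimated correlation). None passed over all genes in edgeR, and 9 passed adjusted over the list alone, 8 lower and 1 higher in BALB/c. Over all genes C1qb passed with DESeq2 (adjusted p = 0.0332), and H2-Ab1 with DESeq2 (6.9e-05) and library quality weights (0.00968). C1qb and C1qc, complement subunits made by macrophages, were lower by -1.76 ± 0.43 and -1.34 ± 0.34, and Cd68, Fcer1g, Itgam, Laptm5, Cd52 and Coro1a were the other 6. H2-Ab1, an MHC class II chain, was the one higher, at 68.4 ± 16.1 CPM in BALB/c and 18.3 ± 1.64 CPM in C57BL/6. The most abundant members, Lyz2 and C1qa, had log2 differences of -0.36 ± 0.30 and -1.11 ± 0.44, and Lyz2 has 1 near-identical copy. The listed genes held 0.111 ± 0.0180% of all counts in BALB/c and 0.172 ± 0.0432% in C57BL/6 (SD, n = 3 each), and C57BL/6 replicate 1 had the highest share, 0.201%. C57BL/6 replicate 2 held 0.122%, below BALB/c replicate 1 with 0.125%, and the mean of the list there, relative to the mean of the 6 libraries, was -0.20, against 0.87 and 0.52 in C57BL/6 replicates 1 and 3 and -0.50 to -0.33 in BALB/c.

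Of 10 pericyte and smooth muscle markers 8 were lower in BALB/c (camera adjusted p = 3.7e-04, and adjusted p = 0.395 with an estimated correlation). Those that passed adjusted over the list alone were Cnn1 and Actg2, the same genes as in the contractile list. Of 10 endothelial markers 9 were lower, with a median of -0.72 (camera adjusted p = 0.00249, and adjusted p = 0.515 with an estimated correlation), and 0 passed by either adjustment. Without C57BL/6 replicate 1 the camera adjusted p of the endothelial list was 0.0561. Eng, endoglin, had a log2 difference of -0.44 ± 0.35 and Ecscr, an endothelial surface protein, one of -1.06 ± 0.42. The 18 tested mammary epithelial markers had a camera adjusted p of 0.713, and 0 passed by either adjustment. The direction depended on the libraries: the list was higher in BALB/c without BALB/c replicate 1 (camera adjusted p = 0.0149) and lower without BALB/c replicate 2 (0.0120) or C57BL/6 replicate 2 (0.0193). Keratins Krt18 and Krt8 had log2 differences of -0.65 ± 0.79 and -0.47 ± 0.74, and the listed epithelial genes held 0.878 ± 0.589% of all counts in BALB/c and 1.12 ± 0.722% in C57BL/6. Of 8 Schwann cell and nerve markers 0 passed by either adjustment (camera adjusted p = 0.108), with -0.02 ± 0.36 for Pmp22 and -0.59 ± 0.44 for Ncam1.

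**Figure D3:**
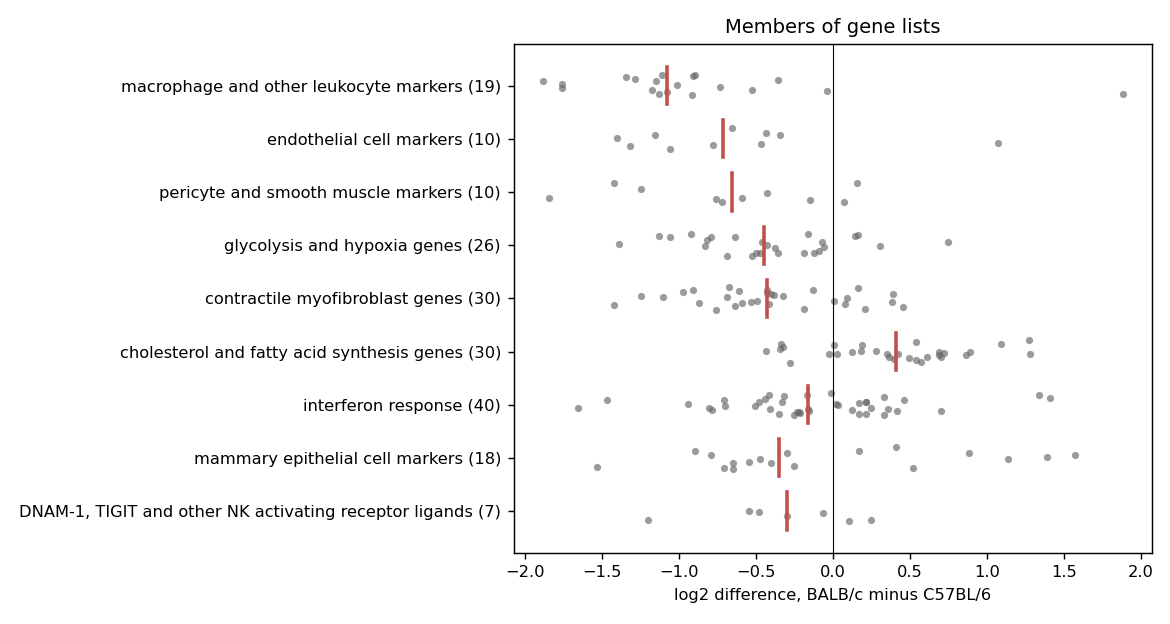
Each point is the log2 difference, BALB/c minus C57BL/6, of a tested member of a gene list, the bar is the median of the list and the number in brackets the members tested. The upper 6 lists passed the camera test with its preset correlation, 5 with medians of -1.08 to -0.43 and the cholesterol and fatty acid list with 0.41; the lower 3 did not.

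Genes of cholesterol and fatty acid synthesis were higher in BALB/c as a list, and genes of glycolysis and hypoxia lower. Of 30 tested genes of lipid synthesis 24 were higher, with a median of 0.41 (camera adjusted p = 0.00489, and adjusted p = 0.463 with an estimated correlation). Fdps and Scd2 had log2 differences of 0.40 ± 0.26 and 0.42 ± 0.75. The mean of the lipid list in C57BL/6 replicate 1 was -0.77, against -0.02 and -0.00 in replicates 2 and 3, and without BALB/c replicate 3 its camera adjusted p was 0.0814. Of 26 tested genes of glycolysis and hypoxia 22 were lower, with a median of -0.45 (camera adjusted p = 3.7e-04, and adjusted p = 0.297 with an estimated correlation). Pkm, pyruvate kinase, had -0.53 ± 0.33 and Mif -0.50 ± 0.29. The mean of the glycolysis list was -0.18 in C57BL/6 replicate 1, below BALB/c replicates 1 and 3 at -0.05 and -0.14, and 0.33 and 0.37 in C57BL/6 replicates 2 and 3. In both lists 0 genes passed over all genes or adjusted over the list alone.

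The remaining lists did not pass the camera test. Cell cycle genes had an adjusted p of 0.105 with 0 of 45 past the threshold by either adjustment in edgeR, and cyclin D1, Ccnd1, had a log2 difference of 1.70 ± 0.44 (adjusted p = 0.617 in edgeR and 0.0396 in DESeq2) and Ube2c one of -0.24 ± 0.36. Targets of p53 and senescence genes had 0.417, with -0.34 ± 0.24 for Cdkn1a and 0 of 24 past the threshold by either adjustment in edgeR, while Plk3, named after its values were seen, passed over all genes with quality weights (0.0262). Heat shock genes and chaperones had 0.574, with -0.19 ± 0.29 for Hsp90ab1 and -0.24 ± 0.28 for Serpinh1. Hspa8, a constitutive chaperone, passed adjusted over the list alone and was lower in BALB/c by -1.66 ± 0.33 (adjusted p over all genes 0.247 in edgeR, 0.00145 in DESeq2 and 0.0287 with quality weights). Unfolded protein and ATF4 response genes had 0.108, with 0.26 ± 0.31 for Hsp90b1, and NRF2 and glutathione genes had 0.724, with -0.26 ± 0.37 for the ferritin gene Ftl1, which has 10 near-identical copies, and -0.02 ± 0.26 for Fth1. Immediate early genes had 0.300, with -0.19 ± 0.23 for Ccn1 and -0.49 ± 0.53 for Ier3. These 3 lists had 0 genes past the threshold by either adjustment. Nuclear genes of oxidative phosphorylation had 0.417, with 0.15 ± 0.21 for Atp5b and -0.35 ± 0.22 for Cox6a1 and 0 of 68 past the threshold by either adjustment in edgeR, while Atp5g2, also named after its values were seen, passed over all genes with quality weights (0.0262). Of 77 cytosolic ribosomal protein genes Rpl29 was the 1 past the threshold, over all genes and adjusted over the list alone, and the list had 0.372. Mitochondrially encoded genes are not among the genes of the table used here.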

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

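The library quality weights, the GC and length offset and the principal components without each library were chosen after the data were seen. All 18 genes kept the sign of their log2 difference in the 17 alternatives that could test them. The 18 genes were called again with RLE scaling, without a filter, with DESeq2 and with library quality weights. Upper quartile scaling kept 16, leaving out ribosomal genes 16 of 17 tested, a mean of at least 50 counts 12 of 13 tested, and the GC and length offset 17. Ly6a was called in the fewest alternatives, 6 of 17, and its adjusted p was 0.0575 with upper quartile scaling, 0.0704 with library totals alone, 0.171 with limma-voom, 0.0645 with a mean of at least 50 counts and 0.0520 with ribosomal genes left out. The causes of the changes below were not tested, except that leaving out a library leaves fewer samples.

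Library totals alone gave 11 genes, 6 of them lower in BALB/c, with all 11 changed by at least 1 on the log2 scale. DESeq2 gave 71, 25 higher and 46 lower, and limma-voom 3, 1 higher and 2 lower, each changed by at least 1. Library quality weights gave 57, 25 higher and 32 lower, 55 of them changed by at least 1, and the GC and length offset gave 31, 15 higher, with all 31 changed by at least 1. Leaving out each library in turn gave 0 to 25 genes in all and changed by at least 1, 0 to 9 higher and 0 to 16 lower. The 0 came from edgeR without BALB/c replicate 2, BALB/c replicate 3 or C57BL/6 replicate 3, and no other tool was run there. In these runs 205 to 261 genes had an unadjusted p under 0.05, a share below 0.05 of those tested. The 25 came without C57BL/6 replicate 1, where the biological coefficient of variation was 29.3% against 41.1%.

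With the replicate number as a block (a replicate block) edgeR gave 0 genes past the threshold, 0 higher, 0 lower and 0 changed by at least 1. With the block 158 of 8752 genes had an unadjusted p under 0.05, also a share below 0.05. No other tool was run with the block. The deviations of the libraries showed no pairing by number, though with 3 libraries per strain a weaker pairing could not be excluded. Deviations of same-numbered libraries correlated at -0.42, -0.40 and -0.08 across genes, and BALB/c replicate 1 correlated best with C57BL/6 replicate 2, at 0.58. The block changed no call of a gene list.

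The contractile, pericyte, leukocyte and glycolysis lists stayed past the threshold in 17 alternatives with camera's preset correlation. With an estimated correlation the adjusted p was 0.407 for the contractile list, 0.463 for the leukocyte list, 0.515 for the endothelial list, 0.395 for the pericyte list, 0.463 for the lipid synthesis list and 0.297 for the glycolysis list. In the same order fry gave 0.299, 0.299, 0.374, 0.288, 0.299 and 0.0680 for movement in 1 direction and 0.271, 0.0737, 0.271, 0.0645, 0.354 and 0.211 for change in either direction. With a mean of at least 50 counts the endothelial list had 0.112, and the DNAM-1 and TIGIT ligands and the cell cycle genes 0.0373 each. Cell cycle genes had 0.0250 without a filter. The matrix protease list had 0.0281 with limma-voom, 0.0400 with the GC and length offset and 0.0182 with quality weights. Quality weights also gave 9.3e-04 for the interferon list and for oxidative phosphorylation, 0.0149 for Schwann cell markers, 0.0400 for the unfolded protein list and 1.1e-08 for ribosomal proteins.

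Leaving out each library in turn, camera's adjusted p ran from 0.0309 to 0.445 for Schwann cell markers, 0.0425 to 0.263 for adipogenic genes, 0.00150 to 0.416 for the cell cycle, 6.4e-04 to 0.0814 for lipid synthesis, 0.0381 to 0.526 for ribosomal proteins, 5.5e-05 to 0.0561 for endothelial markers and 0.00408 to 0.946 for collagens. It ran from 2.8e-04 to 0.827 for the interferon list, 0.0481 to 0.624 for matrix glycoproteins, 1.1e-04 to 0.692 for matrix proteases, 0.0108 to 0.898 for oxidative phosphorylation and 0.0381 to 0.448 for the unfolded protein list. The epithelial list ran from 0.0120 to 0.898 and turned from lower to higher in BALB/c without BALB/c replicate 1 (0.0149). The first principal component held 77.4% of the variance of the 1000 most variable genes, and 48.9% to 75.9% without each library in turn, lowest without C57BL/6 replicate 1. In simulated counts with the depth and the spread per gene of these libraries, but no library set apart, 2 of 61 genes changed 2-fold were called. Depth was not varied on its own.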

Other observations

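The tests of alignment loss, shared reads, GC content, depth, epithelial cells and fibroblast share were chosen after the result was seen. The tests of other splits, the second leukocyte list and neighbouring genes were written before.

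Several genes differed between libraries without regard to strain, and they are named here after their values were seen. Gapdh, a glycolytic enzyme, had 3723 and 9577 counts in BALB/c replicate 1 and C57BL/6 replicate 3 and 67, 45, 60 and 76 in the other 4 libraries, and it has 89 near-identical copies. Mir692-1, with 12 copies, had 2347, 4387 and 12693 counts in BALB/c replicates 1 and 3 and C57BL/6 replicate 3, and 81, 83 and 55 in the others. Cth, an enzyme of cysteine synthesis, had 197 counts in BALB/c replicate 1 and 109 in C57BL/6 replicate 2, and 2 to 34 in the other 4 libraries. Fgf21, a stress-induced hormone, had 123 and 137 counts in the same libraries, against 7 to 38. These are also the libraries with the fewest counts of keratins. Wnt7a and Itgb4, genes of the basal epithelium, were low in both, with 5 and 3 counts of Wnt7a against 24 to 190 elsewhere and 52 and 71 of Itgb4 against 296 to 1237.

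The strain split gave 18 genes past the threshold in edgeR, and the highest of the other 9 splits of the 6 libraries into 3 and 3 gave 0, with 21 to 696 genes at an unadjusted p under 0.05. With DESeq2 the strain split gave 71 and the highest other 34. In edgeR 1 of the 10 splits, the strain split itself, gave as many, and 10 splits are too few for a share under 0.05. The strain split gave 6 lists past the threshold in camera, 4 of the 10 splits gave as many and the highest gave 13, and here too the splits are too few for a share under 0.05. BALB/c replicates 1 and 3 with C57BL/6 replicate 2 against the rest gave 696 genes at an unadjusted p under 0.05, against 338 for the strains, which points to a structure of the libraries other than strain.

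The first pattern weighed is the set of 18 genes, which differed by 5.41-fold or more. A loss of BALB/c reads in alignment to a C57BL/6 reference cannot by itself raise a gene in BALB/c. This argues against loss alone for the 6 genes higher in BALB/c. It does not cover reads placed at another gene instead of being lost, which were not tested. For the 12 lower genes it cannot be told apart from low expression, since the exact two-sided binomial p of the split of 6 and 12 was 0.238 and reads were not analysed here. Reads shared with a near-identical copy may account for part of the set, since 6 of the 18 genes, or 33.3%, had such a copy against 7.51% of the other tested genes (Fisher's exact p = 0.00154), but the other 12 had none within the limits of the search. The 6 include Ly6a, AI506816 and Stmn1, whose longest matches were only 116, 87 and 60 nt. The test was not repeated with longer matches alone. An inherited difference in expression, which the strains of the design would give, stays open for the set and was not tested apart from these.

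The second pattern is C57BL/6 replicate 1, which lay apart from the other 5 libraries. A GC or length trend explained 50.3% of its deviations, but once the trend of each library was removed its mean correlation with the others was 0.843, still below the lowest of theirs, 0.892, which argues against that trend as the whole cause. Lower depth is argued against by the 3 libraries with fewer counts, all of which correlated better with the others. More epithelial cells are argued against by C57BL/6 replicate 3, whose epithelial markers lay as far above replicate 2 (1.57 on the log2 scale) as those of replicate 1 did (1.67), while the 657 genes at least 4-fold lower in replicate 1 than in replicate 2 had a median difference of -0.50 (quartiles -0.80 and -0.24) between replicates 3 and 2, 16.3% of that between 1 and 2. In BALB/c, where replicates 2 and 3 lay above replicate 1 in epithelial markers by 2.18, the same genes had a median of -0.41 between them. The design names no group that sets this library apart, so the origin of the trend stays open and no biological explanation from the design was tested.

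The third pattern is the lower level of leukocyte markers in BALB/c. A second list of 29 leukocyte genes, fixed before it was tested and sharing none with the first, had a median log2 difference of -0.69 with 24 members lower, so fewer leukocytes left in the BALB/c cultures is a candidate explanation. The GC trend of C57BL/6 replicate 1 is argued against by the first list, whose median was -0.75 without that library. Endothelial and pericyte markers were lower in BALB/c too, with medians of -0.72 and -0.66, so a lower share of fibroblasts in C57BL/6 cannot be told apart from fewer leukocytes in BALB/c, and the strain difference of epithelial markers lay above that of leukocyte markers by 0.71 with a standard error over libraries of 0.83. General fibroblast markers held 1.515 ± 0.477% of all counts in BALB/c and 1.358 ± 0.651% in C57BL/6 (SD, n = 3 each). This spread is too wide to decide on the share of fibroblasts. The most abundant transcript of the leukocyte list, Lyz2, differed by only -0.36 ± 0.30. Its 1 near-identical copy, matching over 497 nt, makes its count uncertain. H2-Ab1 went the other way, and the list did not hold with an estimated correlation (adjusted p = 0.463 in camera). A change within the leukocytes thus stays open, as does the magnetic separation of the design text, whose target is not given. The listed genes held at most 0.201% of the counts of a library, and C57BL/6 replicate 2, with 0.122%, lay below BALB/c replicate 1, with 0.125%.

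A further hypothesis was that strain differences come in blocks of neighbouring genes, as inherited segments would give. The 100 genes with the smallest p held 21 pairs within 1 Mb, against a median of 10 and a 95th percentile of 17 in 10000 random sets (one-sided permutation p = 0.00870), and 14 of the 21 pairs had the same direction. Ly6a with Ly6c1 and C1qb with C1qc were pairs of the same direction, and Cap1 with Ppt1 a pair of opposite direction. The top 100 genes of the other 9 splits held 8 to 23 pairs, so 1 split without regard to strain gave as many, and the hypothesis cannot be told apart from neighbours that vary together for other reasons.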
